A study of Zea mays with 27 samples.

How the data were processed

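The data are 27 small RNA libraries from maize leaves at stage V5/V6, of greenhouse plants that carried a single copy of a transgene, made from total RNA, per the labels. The series' design text names the Illumina TruSeq preparation. The labels name 6 constructs and, for each, a cry gene (a Bacillus thuringiensis insecticidal protein gene, cry1Fa or cry1Ab) and the design of its coding sequence, Zm, ZmMod or ZmHiGC. They do not give the sequences, and they do not spell these design names out. Of the libraries, 22 came from a single plant each and 5 from pools of 6 plants of the T3 generation of pDAB447. Every single-plant group came from 1 transformation event, so construct and event cannot be separated. Nothing says how the plants of an event are related or handled, and p-values therefore measure only the spread between plants of that event.

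Each deposited file lists the different sequences (tags) of a library with their counts, and per the file headers these are raw numbers of reads per unique tag with no normalization. Whole-number totals of 11797566 to 29743815 per library fit that unit. The tool that removed adapters, and any aligner or genome build, are not given in the sources used here, and no genome was used here. Plant libraries held tags of 14 to 29 nt plus reads of 35 nt, taken here as inserts at least as long as the read. The pools reached 75 nt, so they came from a run of another read length. Tags with an unread base were dropped. All levels are in RPM, scaled to the 18 to 30 nt reads of the same library and computed here from the deposited counts. These numbered 1500698 to 12153428 per plant and 5405626 to 8132318 per pool. A floor of 3 reads corresponded to 0.247 to 2.00 RPM. Reads without molecular identifiers are not independent molecules, so exact (Clopper-Pearson) 95% intervals and floors cover counting error only.

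The cry coding sequences were rebuilt from the tags. The Cry1Fa and Cry1Ab protein sequences, the 35 mature miRNAs and the rRNA and tRNA stretches used as a sign of RNA quality were written from general knowledge before the data were examined. A tag of at least 21 nt was read as cry when at least 7 whole codons translated exactly, on either strand, into the Cry protein of its label. Such tags in at least 2 libraries of a design were seeds, which tags with 5 matching codons and an overlap of 12 bases extended. Reads of 18 to 30 nt lying without mismatch in the rebuilt sequence, on either strand, gave the cry level. Direct translation, which needs no rebuilt sequence, was set as the other reading before the sequences were rebuilt. The seeds, the extending tags and the tags read by direct translation were restricted, after the data were seen, to those with at most 20% of their RPM in libraries of the other cry gene. This set aside 242 tags with 6486 reads for cry1Ab, some present in all 27 libraries, and 128 tags with 249 reads for cry1Fa. The step that extends seeds was also revised after the data were seen.

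The strand, size and position of cry reads were added after the data were seen. They were read on longer sequences rebuilt per construct from seeds in 1 library or more, with the 20% limit applied to the matched tags as well. That last limit was set after the strands of pDAB447 had been seen, because an antisense family of tags shared by all libraries had entered its sequence. The sequence rebuilt per design did not have the limit on matched tags, but its seeds did. Sizes by direct translation were read on tags that start at a codon, where every length has the same chance, and also, as an alternative added after the data were seen, on tags of every frame. The background of direct translation without the limit was read in the libraries of the other cry gene. On simulated cry reads, 4.05%, 58.6% and 100% of the cry tags were recovered at 150, 600 and 2400 reads, with 0 background tags, so levels resting on few reads are underestimates and depend on the rebuilt length. Positions are bases of the coding sequence counted from 1 at the start codon, and the toxin core is bases 1 to 1848.

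Group differences in cry level used log2(RPM + 0.1) and a two-sided exact permutation test, with Benjamini-Hochberg adjustment over 6 contrasts of constructs. The smallest exact p was 0.1 for 3 against 3 plants, 0.0357 for 5 against 3 and 0.00794 for 5 against 5. The share of 24-nt reads was tested in the same way. Fold differences of cry levels are on the log2(RPM + 0.1) scale.

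Single tags were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM normalization in a single fit of the 22 plants with a mean per construct (16 residual degrees of freedom, common dispersion 0.288). Tags of 18 to 30 nt with at least 5 CPM in at least 3 libraries entered, 25505 of 13090659 different tags, holding 63.5% of the 18 to 30 nt reads. Calls are at an adjusted p under 0.05. The listed miRNAs were adjusted over the list alone and over all tags. On counts simulated for pDAB441 against pDAB443 with 25505 tags, the test recovered 0%, 8%, 68% and 72% of 50 tags changed 2, 4, 8 and 16-fold. For pDAB447 against pDAB448 it recovered 0%, 26%, 52% and 86%. It called 5 and 4 of the 25305 unchanged tags.

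The rule for named items was set before the data were examined. It takes every listed miRNA past the threshold over the list alone, the cry sequences, the 10 most abundant miRNAs and, per contrast, at most 2 tags of no list that rose and 2 that fell most without overlap between the plants. Tags later found to belong to aad-1 were chosen by this rule. The gene aad-1, coding for the herbicide-tolerance enzyme aryloxyalkanoate dioxygenase, is not named in the labels. Its protein sequence was written from general knowledge after the changed tags had been seen, and its coding sequence was rebuilt from tags as for cry.

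Alternatives were other normalizations, DESeq2 1.42.0, another filter on low counts, a fit of the compared plants alone, plant number as a block, size classes, denominators, a pseudocount of 1 RPM and leaving out each library. Alternatives added after the data were seen were sequences rebuilt per construct, antisense reads only, no limit on shared tags (for rebuilt sequences and for direct translation), tags of 20 to 24 nt only, and the share of full-length reads as a covariate. Replicate libraries differed by a chi-square per tag of 5.74 to 109, so none was a repeat deposit. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.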

Results

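Small RNAs were sequenced from leaves of maize plants carrying 1 of 6 transgene constructs, and the series asks whether the base composition of a coding sequence bears on small RNA silencing of the transgene. The cry1Fa gene was carried in the Zm design by pDAB435 (n = 5 plants) and pDAB443 (n = 3) and in the ZmMod design by pDAB441 (n = 3). The cry1Ab gene was carried in the Zm design by pDAB448 (n = 3), in the ZmMod design by pDAB449 (n = 3) and in the ZmHiGC design by pDAB447 (n = 5). In addition, 5 pools of 6 T3 plants each covered 5 events of pDAB447, namely 002, 010, 012, 023 and 030, of which 002 was the event of the single plants. Reads of 18 to 30 nt numbered 5697249 to 8171133 in pDAB435, 6240432 to 12153428 in pDAB441, 5561717 to 6579004 in pDAB443, 2293869 to 8540037 in pDAB447, 1736358 to 2222679 in pDAB448 and 1500698 to 5239616 in pDAB449. Full-length reads of 35 nt took 35.7% ± 5.56 (SD, n = 3) of pDAB441 libraries, 45.1% ± 13.3 (n = 5) of pDAB435, 53.6% ± 9.57 (n = 3) of pDAB443, 61.1% ± 16.4 (n = 5) of pDAB447, 82.6% ± 4.38 (n = 3) of pDAB449 and 87.6% ± 2.39 (n = 3) of pDAB448.

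The cry coding sequences differed in composition where tags allowed them to be rebuilt. The ZmHiGC design of cry1Ab was rebuilt over 1637 bases with 58.7% G and C and 86.2% G or C at the last position of codons. The cry1Ab Zm design had 49.5% G and C over 545 bases, and cry1Ab ZmMod had 55.1% over 227 bases. At the 524 bases known in both, ZmHiGC and Zm were 83.2% identical and held 56.3% and 49.4% G and C. At the 131 bases known in both, cry1Ab Zm and ZmMod were 81.7% identical and held 53.4% and 51.1%. For cry1Fa, ZmMod had 51.8% over 751 bases. The sequences of pDAB435 and pDAB443, which share the label cry1Fa Zm, were only 84.0% identical over the 1126 bases known in both, with 61.1% and 56% G and C there. Of the codons rebuilt, 581 of 581 for cry1Fa Zm and 537 of 538 for cry1Ab ZmHiGC gave the residue of the Cry protein. Only tags whose whole codons translate into that protein were used, so this agreement was fixed in advance and does not test the rebuilt sequences. Because pDAB435 and pDAB443 differed in sequence, levels of cry1Fa are given on the sequence rebuilt per design, as planned, and on the sequence rebuilt per construct.

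Cry1Fa small RNAs were scarcer in plants of the ZmMod design than in plants of either Zm construct. They made up 16.0 RPM ± 8.29 (SD, n = 3) in pDAB441, 64.5 RPM ± 13.3 (n = 3) in pDAB443 and 1531 RPM ± 1817 (n = 5) in pDAB435. On the sequence rebuilt per construct, the pDAB443 level was 338 RPM ± 60.0 and the pDAB435 level 1585 RPM ± 1879. Sequences of the other cry gene, the background of the measurement, gave at most 12.4 RPM in any library, in pDAB435 plant 03. In pDAB441 the antisense strand held 30.1% ± 8.45 (SD, n = 3) of cry1Fa reads, and 21 and 22 nt, the sizes of small RNAs that direct cleavage of transcripts, held 54.3% ± 17.4. In pDAB443 these shares were 39.6% ± 1.94 and 88.1% ± 3.33 (n = 3), and in pDAB435 43.2% ± 16.3 and 77.1% ± 19 (n = 5), all on the sequences rebuilt per construct. On those rebuilt per design the antisense shares were 39.3% ± 8.16, 67.2% ± 4.67 and 43.3% ± 16.1 in the same order.

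Between pDAB441 and pDAB443 the cry1Fa level differed by -2.14 on the log2 scale (SE 0.52), a level 4.40-fold lower in pDAB441. The 3 plants of each group did not overlap, which 3 against 3 plants give by chance in 10% of cases, and the exact permutation p was 0.1, the smallest possible (adjusted p = 0.12). On the sequences rebuilt per construct the difference was -4.53, and by direct translation -3.74, each with an exact permutation p of 0.1. The level of pDAB441 was 41.8-fold lower than that of pDAB435, a log2 difference of -5.39 (SE 1.19; exact permutation p = 0.0357, adjusted p = 0.0714 over the 6 contrasts), with every pDAB441 plant below every pDAB435 plant. This fold rests on rebuilt sequences of unequal length, 751 bases for cry1Fa ZmMod and 1752 for cry1Fa Zm. By direct translation the levels were 12.9 RPM ± 5.50 (SD, n = 3) in pDAB441 and 717 RPM ± 844 (n = 5) in pDAB435, again without overlap. The 21 and 22 nt share was -33.8 points apart between pDAB441 and pDAB443 (SE 10.2; exact permutation p = 0.1), and the antisense share -9.52 points (SE 5.01; exact permutation p = 0.3), or -27.9 points with no overlap (SE 5.43; exact permutation p = 0.1) on the sequences rebuilt per design. Levels of pDAB441 rested on 47 to 293 reads per plant and its shares on 79 to 390.

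**Figure D1:**
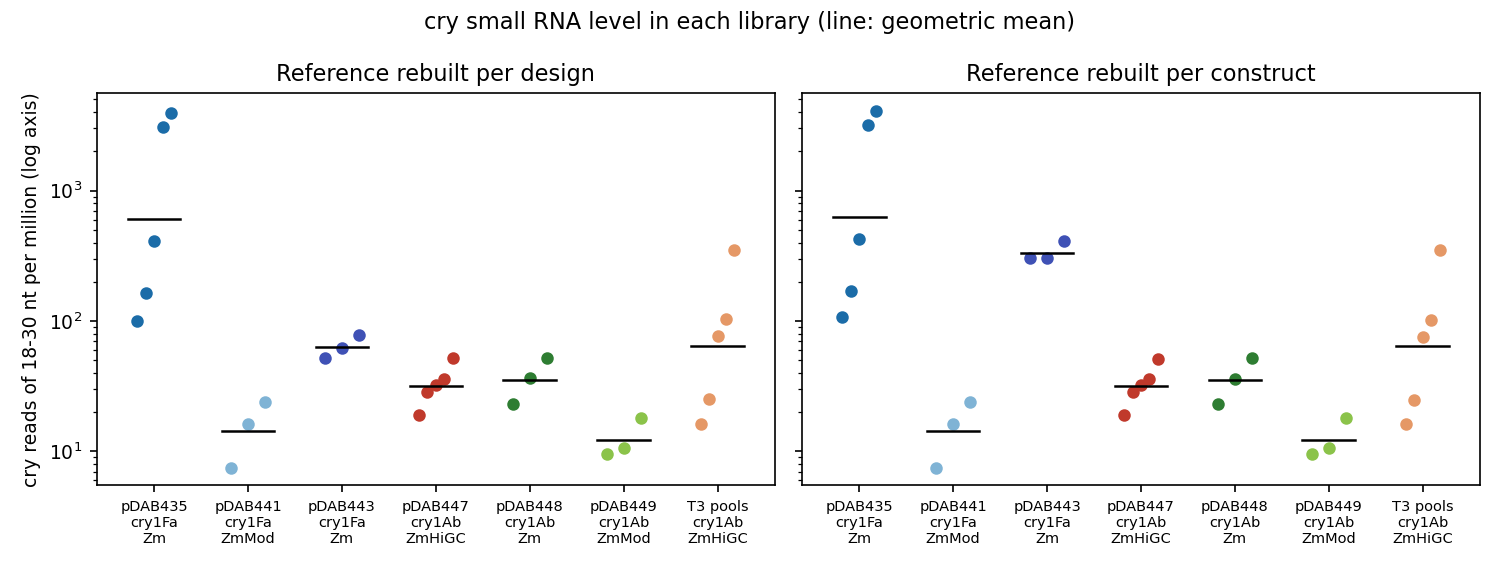
Level of cry small RNAs per library in RPM (of the 18 to 30 nt reads) on a log axis, on the sequences rebuilt per design and per construct, with each point a library and each line a geometric mean. The pDAB435 plants range from 100.2 to 3912 RPM on the sequence rebuilt per design, and all pDAB441 plants lie below them.

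The constructs pDAB443 and pDAB435 share the cry1Fa Zm label but differed in coding sequence as well as in construct and event. Cry1Fa small RNAs were 9.50-fold lower in pDAB443 than in pDAB435 on the sequence rebuilt per design, a log2 difference of -3.25 (SE 1.09; exact permutation p = 0.0357, adjusted p = 0.0714). On the sequences rebuilt per construct the difference shrank to -0.91 (SE 1.08; exact permutation p = 0.607), and by direct translation to -0.83 (exact permutation p = 0.643). The antisense share of pDAB443 was -3.64 points from that of pDAB435 (exact permutation p = 0.75) per construct and 23.9 points above it (exact permutation p = 0.0357, adjusted p = 0.0714) per design. The pDAB435 plants themselves spread widely, with 100.2 RPM in plant 01, 164 in plant 05, 411 in plant 04, 3068 in plant 12 and 3912 in plant 03. Their antisense shares were 40.0%, 17%, 46.4%, 57.7% and 55.0% in the same order. The spread within pDAB435 was thus wider than the difference between the constructs.

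Cry1Ab small RNAs were low in both the Zm and the ZmMod design, at 37.3 RPM ± 14.6 (SD, n = 3) in pDAB448 and 12.7 RPM ± 4.59 (n = 3) in pDAB449. The level in pDAB449 was 2.87-fold lower, a log2 difference of -1.52 (SE 0.44; exact permutation p = 0.1, the smallest possible, adjusted p = 0.12). By direct translation, which does not depend on the 545 and 227 bases rebuilt for these designs, the levels were 31 RPM ± 7.04 and 17 RPM ± 5.93 and the difference was -0.90 (exact permutation p = 0.1), or -0.11 (exact permutation p = 0.9) without the limit on tags shared with cry1Fa libraries. Both designs had reads of both strands and of the sizes 21 and 22 nt. The antisense share was 46.7% ± 12.0 in pDAB448 and 37.2% ± 4.71 in pDAB449 (SD, n = 3 each; exact permutation p = 0.3), and the 21 and 22 nt share 56.1% ± 15.8 and 59.3% ± 6.13 (exact permutation p = 0.8). Levels rested on 40 to 108 cry reads per pDAB448 plant and 23 to 50 per pDAB449 plant, and shares on 44 to 140 and 36 to 119. Whether the effect of ZmMod against Zm differed between the genes could not be decided. The permutation shuffled plants within each contrast, which tests for no effect in either gene rather than for equal effects. With pDAB443 as the cry1Fa Zm group, its p cannot fall below 0.1, since both contrasts separate the plants in the same direction. The interaction was -0.62 for pDAB441 against pDAB443 (exact permutation p = 0.66) and -3.86 for pDAB441 against pDAB435 (exact permutation p = 0.141). On the sequences rebuilt per construct these were -3.02 (exact permutation p = 0.14) and -3.94 (0.136), and by direct translation -2.84 (0.1) and -3.68 (0.102).

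The 5 plants of pDAB447, all of event 002 of the ZmHiGC design, carried cry1Ab small RNAs at 33.7 RPM ± 12.1 (SD, n = 5). Few of them had the sizes 21 and 22 nt, and once tags shared with cry1Fa libraries had been set aside almost all were sense. With that limit the antisense share in pDAB447 was 2.11% ± 1.14 (SD, n = 5), from 0.388% (exact 95% interval 0.00981% to 2.14%) in plant 03 to 3.36% (1.10% to 7.66%) in plant 05. Antisense cry1Ab reads then reached 0.724 RPM ± 0.360 in pDAB447, against 22.5 RPM ± 16.0 in pDAB448 and 8.58 RPM ± 2.99 in pDAB449 (n = 3 each). The 21 and 22 nt sizes held 12.4% ± 4.05 of the pDAB447 reads.

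The antisense share of pDAB447 was -44.6 points from that of pDAB448 (SE 6.93) and -35.1 points from that of pDAB449 (SE 2.77), each with an exact permutation p of 0.0357, the smallest possible, and an adjusted p of 0.107. The 21 and 22 nt share differed by -43.7 points (SE 9.28) and -46.9 points (SE 3.97), with the same exact permutation p of 0.0357 and adjusted p of 0.107. In each case every pDAB447 plant lay below every plant of the other construct. The antisense differences rested on the limit on tags shared with cry1Fa libraries, which was set after the strands had been seen. Without it they were -3.59 points (exact permutation p = 0.786) and 5.57 points (exact permutation p = 0.464), and by direct translation 3.01 points (exact permutation p = 0.786) and -15.5 points (exact permutation p = 0.107). By direct translation without the limit, antisense Cry1Ab reads were 37.6 RPM in pDAB447, 29.2 in pDAB448 and 35 in pDAB449, and cry1Fa plants, which lack the gene, averaged 40.3 to 46.7 RPM per construct. The 21 and 22 nt differences without the limit were -33.2 and -31.4 points over directly translated tags that start at a codon (27 to 87 reads per pDAB447 plant, 22 to 46 per pDAB448 plant and 17 to 62 per pDAB449 plant). Over such tags of every frame they were -19 and -14.5 points (exact permutation p = 0.0357 for all 4). Antisense reads of 21 and 22 nt alone were 0.422 RPM ± 0.322 in pDAB447 (SD, n = 5), 7.97 RPM ± 4.51 in pDAB448 and 5.33 RPM ± 1.42 in pDAB449 (n = 3 each). Among cry1Fa plants they reached 12.6 RPM in pDAB435, 2.92 in pDAB443 and 0.658 in pDAB441. These levels were not tested.

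In total cry1Ab level pDAB447 did not differ detectably from pDAB448, at -0.14 on the log2 scale (SE 0.41; exact permutation p = 0.679). It was 2.60-fold higher than pDAB449, a log2 difference of 1.38 (SE 0.36; exact permutation p = 0.0357, adjusted p = 0.0714), on rebuilt sequences of unequal length. By direct translation that difference was 0.67 (exact permutation p = 0.179), and without the limit on shared tags 0.44 (exact permutation p = 0.0357). With 21 and 22 nt reads alone pDAB447 was below both, by -2.44 from pDAB448 and -1.0 from pDAB449 on the log2 scale (exact permutation p = 0.0357 each, adjusted p = 0.0536).

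**Figure D2:**
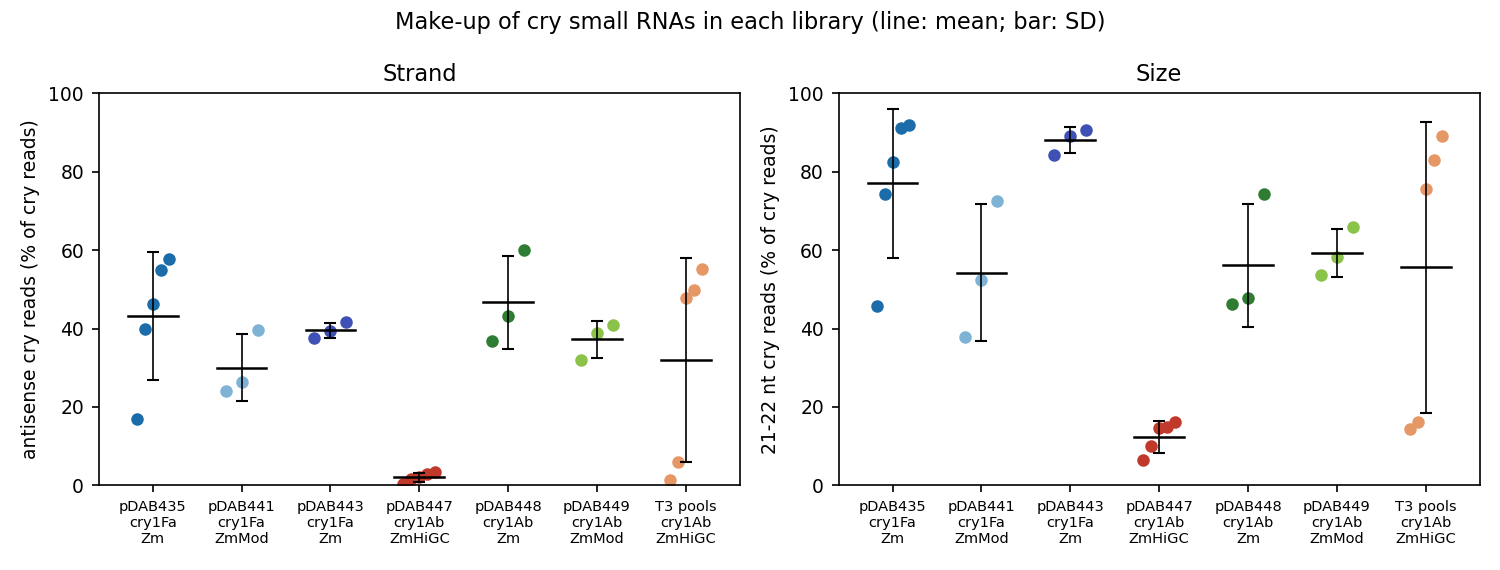
Antisense share and 21 and 22 nt share of cry reads per library, in percent, with means and SD by group, on the sequences rebuilt per construct. The 5 pDAB447 plants have antisense shares of 0.388% to 3.36%, and the T3 pools range from 1.48% to 55.1%, all with tags shared with libraries of the other gene set aside.

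The T3 pools of pDAB447 differed from event to event. The pool of event 002, the event of the plants, held 25.4 RPM of cry1Ab small RNAs with an antisense share of 1.48% (exact 95% interval 0.306% to 4.26%), and that of event 023 held 16.1 RPM with 6.04% (2.80% to 11.2%). The pool of event 010 reached 351 RPM with 55.1% antisense (52.8% to 57.3%), that of event 030 reached 103 RPM with 47.9% (44.5% to 51.4%) and that of event 012 reached 76.2 RPM with 49.8% (45.5% to 54.1%). Reads of 21 and 22 nt made up 14.3% and 16.1% in the pools of events 002 and 023, and 89.2%, 75.6% and 83.0% in those of events 010, 030 and 012. Over all pools against all pDAB447 plants the level differed by 1.01 on the log2 scale (SE 0.82; exact permutation p = 0.27). The antisense share differed by 30.0 points (SE 11.6; exact permutation p = 0.0397, n = 5 each), but by 13.4 points (exact permutation p = 0.103) without the limit on shared tags and 6.96 points (exact permutation p = 0.341) by direct translation without it. The 21 and 22 nt share differed by 43.2 points (SE 16.7; exact permutation p = 0.0556; 36.3 points, p = 0.0317, without the limit). The antisense difference passed without the pool of event 002 (exact permutation p = 0.0159) and not without any other library (0.0635 to 0.0794), and the 21 and 22 nt difference passed without pDAB447 plant 05 (0.0476) or without the pool of event 002 (0.0317). Generation, pooling and read length also differed between the plants and the pools.

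Along the gene, cry small RNAs lay mostly from base 925 onward in 5 constructs, a part that includes reads past the toxin core. The rebuilt sequences ran beyond base 1848 in every construct but pDAB449, up to base 3486 in pDAB435. In pDAB447 the share of that part hung on the limit on shared tags. With the limit that part held 95.5% ± 1.38 (SD, n = 3) of cry reads in pDAB443, 82.2% ± 18.7 (n = 5) in pDAB435, 72.2% ± 10.1 (n = 3) in pDAB441, 79.6% ± 3.89 (n = 3) in pDAB448 and 79.8% ± 10.3 (n = 3) in pDAB449, but 41.5% ± 7.04 (n = 5) in pDAB447. In the pools it ranged from 38.9% to 96.0%. Without the limit it held 57.1% to 77.1% in the pDAB447 plants and 64.3% to 96.2% in the pools, and by direct translation without it 68.5% to 86.1% in the pDAB447 plants. These shares follow the stretches that could be rebuilt as well as the reads in them, and they were not tested.

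**Figure D3:**
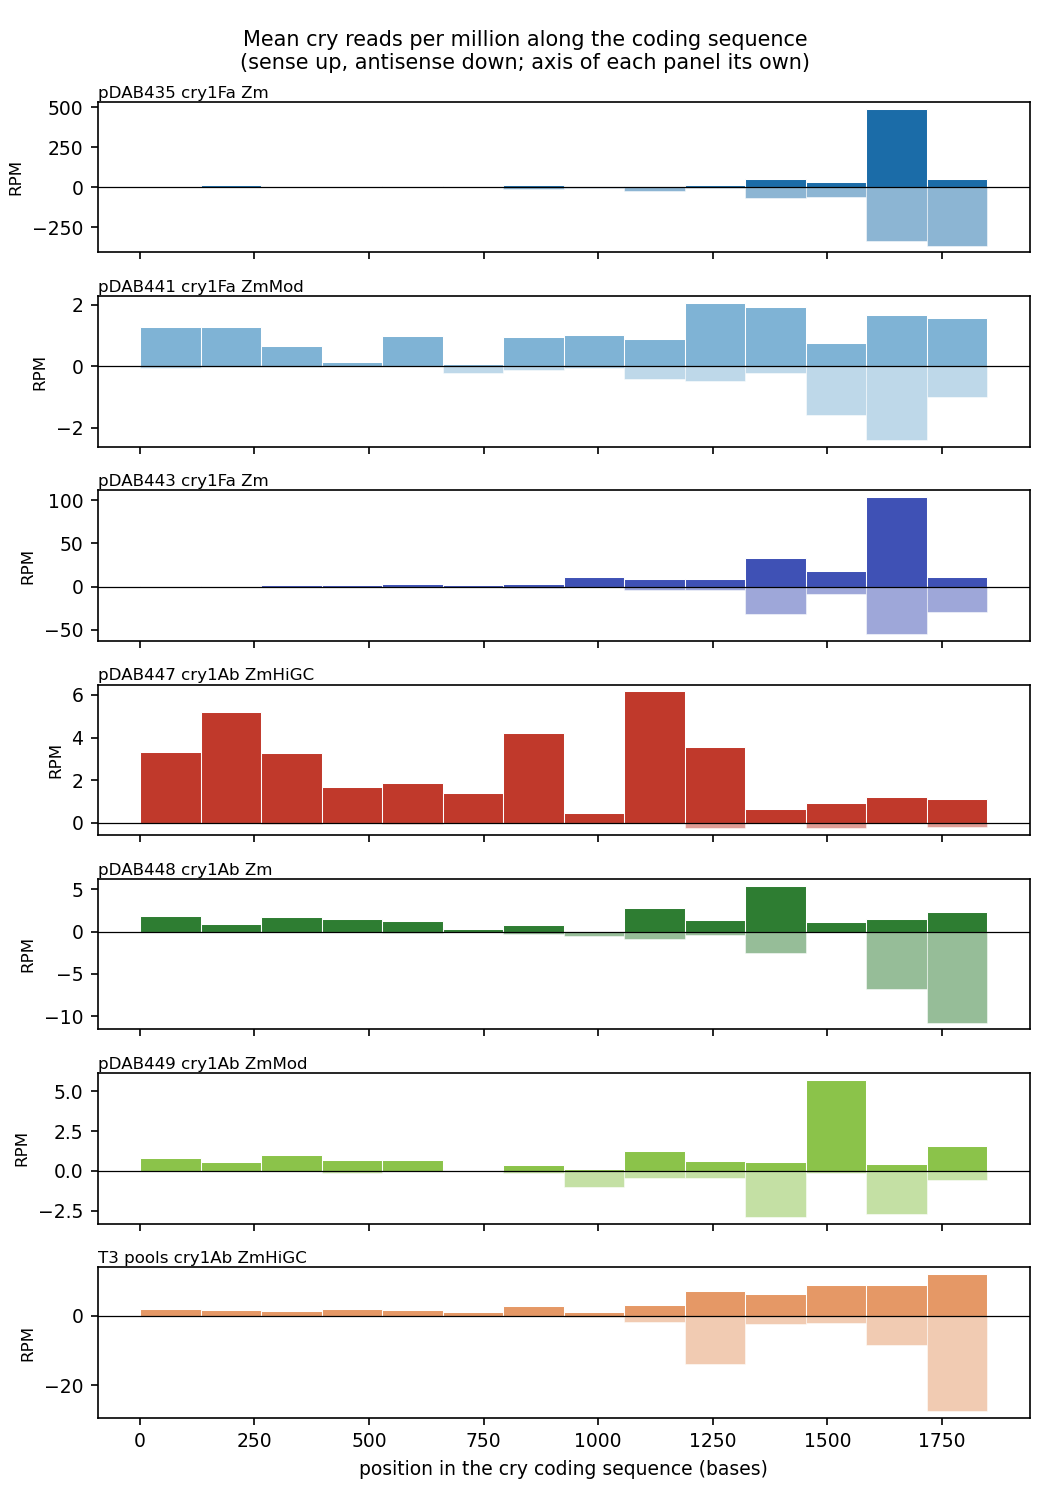
Mean RPM of cry reads in 14 bins over bases 1 to 1848 of the coding sequence, sense above and antisense below the axis. Each group has a separate vertical scale, and the last bin also holds all reads past base 1848. In pDAB435 and pDAB443 both strands are highest toward the last bins. In the pDAB447 plants almost no antisense reads appear once tags shared with cry1Fa libraries are set aside.

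Small RNAs of 24 nt, the size tied to DNA methylation of transposons, made up 14% to 27.1% of the 18 to 30 nt reads of single plants. The 24-nt share of 18 to 30 nt reads was 23.0% ± 2.82 (SD, n = 5) in pDAB447, 22.7% ± 3.90 (n = 3) in pDAB441, 21.1% ± 0.372 (n = 3) in pDAB443, 19.9% ± 2.87 (n = 3) in pDAB449, 19.6% ± 3.73 (n = 5) in pDAB435 and 16.6% ± 3.29 (n = 3) in pDAB448. The difference with the lowest exact permutation p was that of pDAB447 from pDAB448, 6.48 points (SE 2.28; p = 0.0714, adjusted p = 0.429). The other 5 contrasts had exact permutation p-values of 0.2 to 0.8, and 3 against 3 plants cannot go below 0.1.

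The most abundant listed miRNAs were miR166, miR168 and miR156. Over the 22 plants miR166, which targets HD-ZIP III leaf polarity genes, had 11517 RPM, miR168, which targets AGO1, had 1829 RPM, and miR156 of the phase change list, which targets SPL genes, had 741 RPM. The next were miR159, which targets GAMYB genes, at 513 RPM, miR408b at 329, miR166l at 285, miR396, which targets GRF growth regulators, at 184, miR408 at 105, miR396c at 93.6 and miR160, which targets auxin response factors, at 87.5 RPM. Of the 35 listed miRNAs 21 were abundant enough to test. None of the miRNAs of the stress list (2) or of the reproductive phasiRNA triggers (2) was among them.

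Part of the listed miRNAs were higher in pDAB447 plants than in the other cry1Ab constructs, and none passed the test as lower. Against pDAB448, 9 of 21 rose with edgeR when adjusted over the list alone (2 over all tags; 12 at an unadjusted p under 0.05; 12 with DESeq2). They were miR394, which targets an F-box gene of the shoot meristem (log2 1.61 ± 0.47, SE), miR168 (1.2 ± 0.30), miR156 (1.13), miR159 (1.10), miR399e, which targets the PHO2 regulator of phosphate uptake (1.07), miR827 (1.05), miR160 (1.00), miR166l (0.98) and miR396 (0.83). The level of miR168 was 2214 RPM ± 610 (SD, n = 5) in pDAB447, 871 ± 282 (n = 3) in pDAB448 and 1113 ± 170 (n = 3) in pDAB449. It was 2117 RPM in pDAB435, 2000 in pDAB441 and 2207 in pDAB443, so pDAB448 and pDAB449 were the low groups. All listed miRNAs together took at most 1.19% of reads in any pDAB448 or pDAB449 plant and at least 1.21% in any other plant. The pDAB447 plants were not tested against the cry1Fa constructs.

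Against pDAB449, 14 of 21 rose adjusted over the list alone (5 over all tags; 16 unadjusted; 16 with DESeq2). They were miR394 (log2 1.48), miR399e (1.47), miR160 (1.37), the copper miRNAs miR408 (1.31), miR408b (1.25) and miR398 (0.97), miR444 (1.18), miR390, which triggers tasiRNAs against auxin response factors (1.16), miR827 (1.15), miR396 (1.14), miR156 (1.10), miR166l (1.01), miR168 (0.91) and miR159 (0.89). By list, the auxin miRNAs rose in 1 and 2 of 2 tested against pDAB448 and pDAB449, the copper miRNAs in 0 and 3 of 5 and the miRNAs of organ boundary and growth in 3 and 4 of 7. Those of phase change rose in 1 of 3 against each, those of phosphate and sulfate in 2 of 2, that of MYB and TCP in 1 of 1 and that of small RNA machinery in 1 of 1.

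Both comparisons use the same pDAB447 plants, and the share of full-length reads moved with them at 61.1% in pDAB447, 87.6% in pDAB448 and 82.6% in pDAB449. That share is taken here as a sign of RNA quality, without a measure of RNA integrity. Fragments of rRNA and tRNA, another sign of RNA quality, took 0.927% ± 0.207 (SD, n = 5), 1.02% ± 0.226 (n = 3) and 0.994% ± 0.433 (n = 3) of the reads, which differed by less than their spread. The 2 signs did not run together in every construct. In pDAB443 plants 05, 08 and 12 full-length reads took 43.3%, 55.3% and 62.2%, and fragments 1.04%, 0.728% and 0.694%. In pDAB449, plant 11 was the lowest in both. With the share of full-length reads as a covariate 0 miRNAs (5 at an unadjusted p under 0.05) passed against pDAB448 and 4 against pDAB449. With tags of 20 to 24 nt alone 1 and 13 passed, with all tags of at least 30 reads 19 and 17 of 28 tested, and with only the compared plants in the fit 8 and 8. The counts also hung on single plants. Against pDAB448 no miRNA passed without pDAB447 plant 05, pDAB448 plant 05 or pDAB448 plant 12, 1 passed without pDAB447 plant 06 and 14 passed without pDAB447 plant 08. Against pDAB449, 6 passed without pDAB449 plant 11 and 9 without pDAB447 plant 05.

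In the other 4 contrasts no listed miRNA passed with edgeR or with DESeq2. At an unadjusted p under 0.05 edgeR gave 0 for pDAB441 against pDAB443, 1 for pDAB441 against pDAB435, 2 for pDAB449 against pDAB448 and 2 for pDAB443 against pDAB435.

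**Figure D4:**
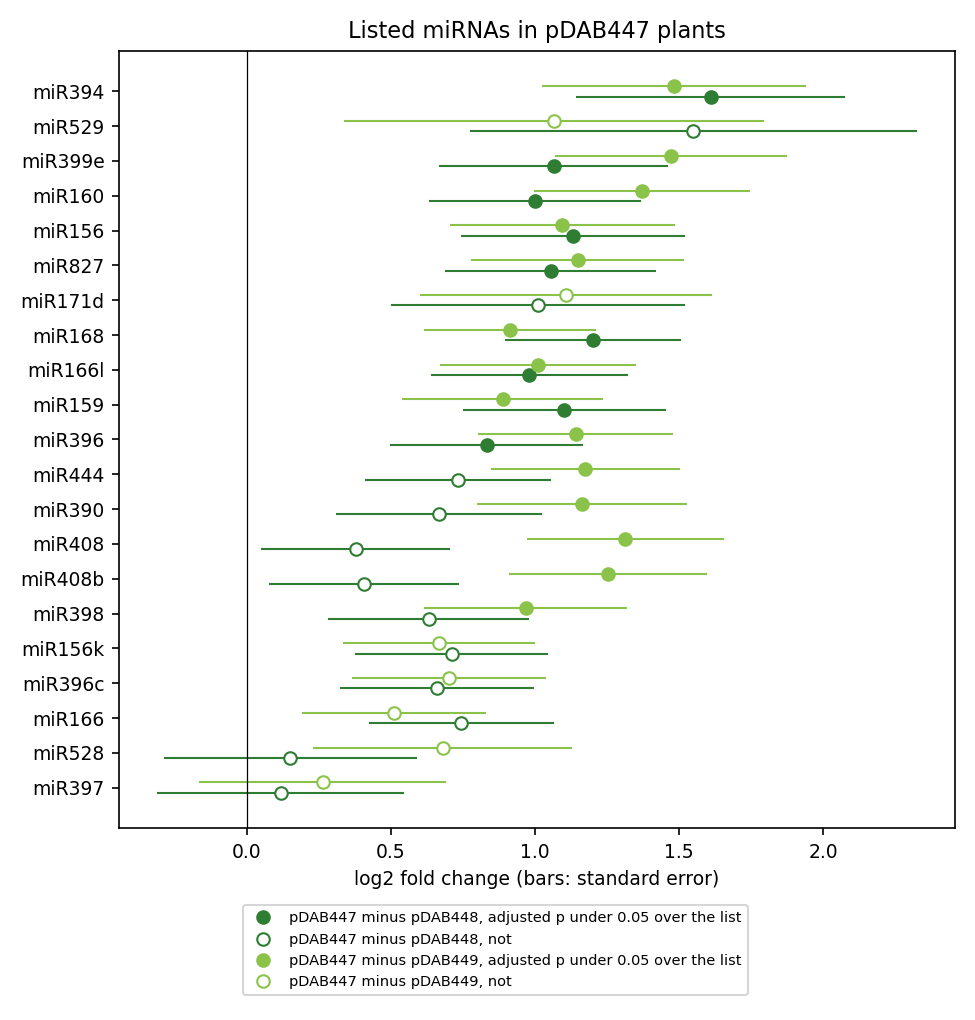
Log2 differences of the tested miRNAs in pDAB447 plants against pDAB448 and pDAB449 plants, in edgeR's fit with SE bars, with filled points for an adjusted p under 0.05 over the list. All 9 and 14 filled points lie above 0, with the highest at 1.61 and 1.48 for miR394, the least abundant of them.

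Of all 25505 tags tested, 2095 differed between pDAB447 and pDAB448, 317 higher and 1778 lower, and 1002 between pDAB447 and pDAB449, 222 higher and 780 lower. The 418 tested tags of aad-1, a herbicide-tolerance gene whose protein translation matched them, fell in both. This gene is not named in the labels and was identified after the changed tags had been seen. Small RNAs of aad-1 made up 47.9 RPM ± 37.3 (SD, n = 5) in pDAB447 plants, 15859 RPM ± 5585 (n = 3) in pDAB448 and 15022 RPM ± 3815 (n = 3) in pDAB449. The aad-1 tag GAGGAACTGAAGCAATGGCTTT had 79.5 RPM ± 33.6 in pDAB448, 66.5 RPM ± 31 in pDAB449 and 0 in the 5 pDAB447 plants, at least 724-fold and 605-fold lower against a floor of 3 reads over the group. The aad-1 tag GTGGAAGAAAGACCAAGTCCT was at least 658-fold lower than in pDAB448, and ATGCACCGTGCTGTTCCTGACTAT at least 569-fold lower than in pDAB449. Fragments of rRNA and tRNA fell in 34 and rose in 1 of 436 tested against pDAB448, and fell in 3 and rose in 4 against pDAB449. Among tags of no list 314 rose and 1326 fell against pDAB448, and 213 rose and 359 fell against pDAB449.

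By length, most of the tags lower than in pDAB448 were of 25 to 30 nt (652) and 21 nt (343), and of the tags lower than in pDAB449 273 were of 21 nt and 161 of 22 nt. Tags of 25 to 30 nt were 9628 of the 25505 tested, a share like theirs among the 1778 lower tags. The aad-1 tags, which all fell in both, included 182 of 21 nt and 107 of 22 nt. Most lower tags of these 2 sizes against pDAB449 were thus of aad-1. Tags of no list that rose included ACTCTGGATTGTAGATTTTGGCCC and CGCGAGACAGTGTAAGATGGAGAC, at 6.95 and 6.23 RPM in pDAB447 and 0 in pDAB448 (at least 14-fold and 12.5-fold higher), and ATCCATATCCTGATGTGTCGGGTC, at 34.5 RPM in pDAB447 and 0 in pDAB449 (at least 102-fold). Relative to library normalization the median of all tested tags lay at -0.17 against pDAB448 and -0.11 against pDAB449. Without pDAB448 plant 12 the first count was 734 and without pDAB447 plant 05 it was 1243, and with DESeq2 the counts were 2869 and 1675. With the share of full-length reads as a covariate they were 1296 (80 higher, 1216 lower) and 762 (81 higher, 681 lower). With only the compared plants in the fit they were 1296 (169 higher) and 875 (86 higher), with tags of 20 to 24 nt alone 1371 (126 higher) and 843 (161 higher), and with all tags of at least 30 reads 1887 and 1561.

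Few tags differed among the other constructs. Between pDAB441 and pDAB443, 10 tags passed (5 higher, 5 lower; 43 with DESeq2, 30 higher and 13 lower; 30 among all tags with at least 30 reads, 6 higher and 24 lower; 4 with the covariate). ATTCCGGAAAATGTTTAGCGCAAC was at 17.6 RPM in pDAB443 and 16.0 in pDAB435 but had 2 reads in all pDAB441 plants. It was lower there by a ratio of 222 (95% Poisson counting interval 61.6 to 1837) and of 206 (57.2 to 1705). ATCCATATCCTTATCTGTCGGGTC was at 25.1 RPM in pDAB441 against 1 read in all pDAB443 plants, a ratio of 423 (75.9 to 16699.9), and it was at 0 in pDAB435, at least 299-fold lower. TTGGAGAGGATTGATGGGATT was at 9.81 RPM in pDAB441 and 0 in pDAB443 (at least 58.7-fold), and GGGAACCGACGGACACACTGACCT was at 3.89 RPM in pDAB443 against 1 read in all pDAB441 plants, a ratio of 97.8 (17.5 to 3861). Leaving out any of the 6 plants left 4 to 6 tags.

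Between pDAB441 and pDAB435, 18 tags passed (9 higher, 9 lower; 42 with DESeq2; 59 among all tags with at least 30 reads, 42 higher and 17 lower; 7 with only the compared plants), and between pDAB443 and pDAB435 15 (7 higher, 8 lower; 47 with DESeq2, 12 higher and 35 lower; 90 among all tags with at least 30 reads, 76 higher and 14 lower; 9 with the covariate). TCCGAATCTGAACCCGACAGCTT was at 19.3 RPM in pDAB441 and 17.3 in pDAB443 against 1 read in all pDAB435 plants, ratios of 631 (95% Poisson counting interval 113 to 24912) and 613 (110.0 to 24210.5). CTCCGAATCTGAACCCGACAGCTT was at 3.83 RPM in pDAB443 and 0 in pDAB435 (at least 45.6-fold), and AGACTAGAGGACGACGAACTAAGT at 7.04 RPM in pDAB435 and 0 in pDAB443 (at least 42.1-fold). The first count was 8 without pDAB441 plant 12 and 9 without pDAB441 plant 02 or 04, and the second was 6, 3 and 4 without pDAB443 plants 05, 08 and 12.

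Between pDAB449 and pDAB448 2 tags passed, and 170 with DESeq2 (11 higher, 159 lower). TTGGAGAGGATTGAGGGGATT was at 4.08 RPM in pDAB449 and 0 in pDAB448 (at least 8.20-fold higher). ATTTGACAAAGACTTTTAGAGCTT was at 7.28 RPM in pDAB448, 6.43 RPM in pDAB435 and 9.84 RPM in pDAB447, and at 0 in pDAB449, pDAB441 and pDAB443. It was thus at least 21.6-fold lower in pDAB449 than in pDAB448 and 29.2-fold lower than in pDAB447, and at least 54.5-fold and 38.5-fold lower than in pDAB435 in pDAB441 and pDAB443. Without pDAB448 plant 03 the count was 297, without pDAB448 plant 05 376, without pDAB448 plant 12 it was 1, and without any of the pDAB449 plants 0 by edgeR, where 1613 to 2272 tags had an unadjusted p under 0.05.

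**Figure D5:**
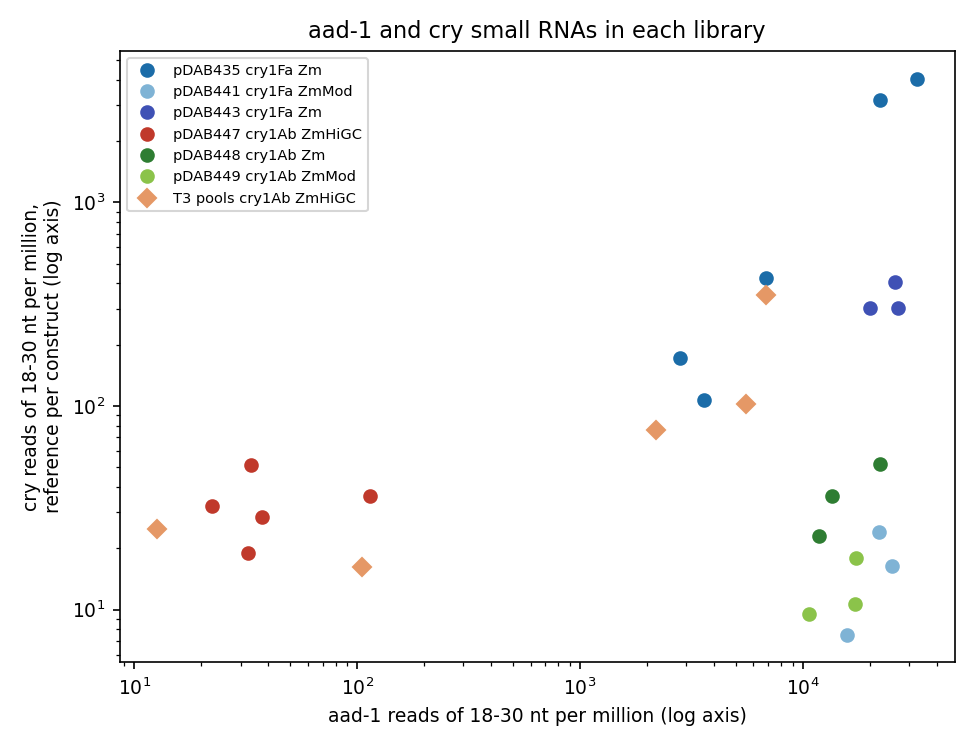
Small RNA levels of aad-1 against those of cry in RPM, both on log axes, with each point a library. The pDAB447 plants and the pools of events 002 and 023 lie at 12.7 to 114 RPM of aad-1, and the other libraries at 2191 RPM or more.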

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

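The search for aad-1 and the test that assigns tags to it were chosen after the result was seen, while the other tests of the tags missing from pDAB447 plants were chosen before.

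A single library stood far from the others of its group in 3 of 30 groups of 5 examined, where chance gives about 1 in 20. The T3 pool of event 010 had 351 RPM of cry1Ab small RNAs, where the other pools had 16.1 to 103. Plant 09 of pDAB447 had 114 RPM of aad-1 small RNAs, where the other plants had 22.2 to 37.5. Plant 03 of pDAB447 had 1.29% of rRNA and tRNA fragments, where the others had 0.802% to 0.861%.

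Reads over 30 nt, which entered no comparison, held the sequence of the cry gene each plant carried. In RPM scaled to such reads, the mean was 33.9 in pDAB435, 11.1 in pDAB441, 14.6 in pDAB443, 21.5 in pDAB447, 14.6 in pDAB448, 5.74 in pDAB449 and 16.9 in the T3 pools, against at most 2.13 in any library for the cry gene it did not carry.

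Small RNAs of the herbicide-tolerance gene aad-1 were far more abundant than those of cry in most plants. Their mean level was 13592 RPM in pDAB435, 20909 in pDAB441, 24200 in pDAB443, 15859 in pDAB448 and 15022 in pDAB449, but 47.9 RPM in pDAB447 plants and 2931 RPM in the T3 pools.

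Of 9731 tags at 5 RPM or more on average in each of the other 5 constructs, 132 had no read in any pDAB447 plant, against at most 1 such tag for any other construct. A loss in the libraries of the pDAB447 plants is argued against by the T3 pool of event 002, another library of that event, where the median of these tags was 0% of their mean in the other plants. A sequence difference linked to event 002 alone cannot be told apart from others, since the median was 36.0%, 11.3% and 29.9% in the pools of events 010, 012 and 030 but 0% in that of event 023. Of the 132 tags, 77.3% lay in the coding sequence rebuilt for aad-1, so a candidate explanation is that siRNAs of this gene were absent or rare in events 002 and 023. Whether the aad-1 gene of those events differed was not tested.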

How the results depend on the processing

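The alternatives that rebuilt sequences per construct, took antisense reads only, lifted the limit on shared tags (also by direct translation), counted directly translated tags of every frame, kept tags of 20 to 24 nt or used full-length reads as a covariate were chosen after the result was seen, as were all strand and size shares. Differences are log2 for levels and points for shares, and where no reason is given the cause was not tested. With 21 and 22 nt reads the level of pDAB447 differed by -2.44 from pDAB448 and by -1.0 from pDAB449. With 24-nt reads the T3 pools differed by -0.23 from the plants, pDAB441 by -0.92 from pDAB443 and pDAB447 by 1.02 from pDAB448. Over 20 to 24 nt reads as denominator pDAB447 differed by -1.35 from pDAB448 and 0.20 from pDAB449. With antisense reads the values were -4.48 (pDAB441 against pDAB443), -0.90 (pDAB443 against pDAB435), -4.74 (pDAB447 against pDAB448) and -3.54 (pDAB447 against pDAB449), and without the limit on shared tags -4.48, -0.90, 0.37 and 1.57, the last of them (exact permutation p = 0.0357) opposite to its value with the limit. By direct translation they were -3.74, -0.83, 0.67 (pDAB447 against pDAB449) and -0.90 (pDAB449 against pDAB448), and by direct translation without the limit -3.74, -0.84, -0.11 (pDAB449 against pDAB448) and 0.33 (pDAB447 against pDAB448). Per construct they were -4.53 and -0.91. With seeds in 1 library they were -4.06, -0.89, 0.61 and -0.91, and without the limit -4.06, -0.89, 0.51 (pDAB447 against pDAB448) and -0.91. The sequence per design joins constructs that differ in sequence, which accounts for the shift of pDAB443.

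Shares moved as follows. By direct translation pDAB449 differed from pDAB448 by -2.0 in 21 and 22 nt and 1.34 in antisense share. Per design the antisense difference was -27.9 for pDAB441 against pDAB443 and 23.9 for pDAB443 against pDAB435, and the 21 and 22 nt difference of the pools was 43.9. Without the limit on shared tags, which lets in an antisense family present in all libraries, the antisense difference was -3.59 (pDAB447 against pDAB448), 5.57 (pDAB447 against pDAB449) and 13.4 (pools, exact permutation p = 0.103), and the 21 and 22 nt difference of the pools was 36.3. By direct translation without the limit the antisense difference was 18.5 (pDAB449 against pDAB448), 3.01 (pDAB447 against pDAB448), -15.5 (pDAB447 against pDAB449) and 6.96 (pools), and the 21 and 22 nt difference of pDAB449 against pDAB448 was -1.76, or -4.50 over tags of every frame. The low antisense share of the pDAB447 plants thus rests on that limit, which also bears on the seeds of every rebuilt sequence. Their lower 21 and 22 nt share kept an unadjusted exact permutation p of 0.0357 without it, which adjustment over the 6 contrasts takes above 0.05. Its differences shrank to -19 (pDAB447 against pDAB448) and -14.5 (pDAB447 against pDAB449) over directly translated tags of every frame. The 24-nt share kept its direction and side of the threshold in 12 of 12 other alternatives.

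Counts of changed tags are given for pDAB441 against pDAB443, pDAB441 against pDAB435, pDAB449 against pDAB448, pDAB447 against pDAB448, pDAB447 against pDAB449 and pDAB443 against pDAB435. Plant numbers did not pair the plants: the mean correlation of 22 same-numbered pairs was 0.0265 (-0.571 to 0.571), 8 were over 0.1 and 4 of 18 plants correlated best with a namesake. With plant number as a block the counts were 1, 2, 0 (1804 at an unadjusted p under 0.05), 626, 652 and 1, and 0 miRNAs for both pDAB447 contrasts by edgeR. With DESeq2 the counts that moved were 43, 42, 170, 1675 for pDAB447 against pDAB449 and 47. With the filter of at least 30 reads they were 30 (6 higher, 24 lower), 59 (42 and 17), 5 (3 and 2), 1561 (190 and 1371) for pDAB447 against pDAB449 and 90 (76 and 14), with 19 of 28 tested miRNAs for pDAB447 against pDAB448. With only the compared plants they were 7 for pDAB441 against pDAB435, 0 for pDAB449 against pDAB448 (939 unadjusted), 1296 for pDAB447 against pDAB448 and 8 miRNAs for pDAB447 against pDAB449. With 20 to 24 nt tags they were 8 for pDAB449 against pDAB448 and 1371 with 1 miRNA for pDAB447 against pDAB448. With the covariate they were 4, 1, 1296 and 9 for pDAB441 against pDAB443, pDAB449 against pDAB448, pDAB447 against pDAB448 and pDAB443 against pDAB435, with 0 and 4 miRNAs for the pDAB447 contrasts. Library totals without TMM gave 1 for pDAB449 against pDAB448.

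Leaving out each library in turn gave, for pDAB441 against pDAB435, levels of -6.03 to -4.71, antisense shares of -19.7 to -9.53, 21 and 22 nt shares of -32.0 to -14.7, 24-nt shares of 0.909 to 4.63 and 8 to 20 tags. In the same order the ranges were -3.90 to -2.58, -10.2 to -0.0109, 3.09 to 14.7, 0.707 to 2.90 and 3 to 13 for pDAB443 against pDAB435, and -2.51 to -1.68, -14.3 to -6.51, -43.0 to -25.6, -0.563 to 3.16 and 4 to 6 for pDAB441 against pDAB443. For pDAB449 against pDAB448 they were -1.83 to -1.24, -14.3 to -2.77, -1.67 to 12.3, 2.11 to 5.24 and 0 to 376. For pDAB447 against pDAB448 they were -0.45 to 0.14, -49.5 to -37.9, -48.6 to -34.6, 5.21 to 8.34 and 734 to 2814, with 0 to 14 miRNAs. For pDAB447 against pDAB449 they were 1.2 to 1.66, -37.8 to -33.3, -49.7 to -43.6, 1.53 to 4.33 and 759 to 1054, with 6 to 16 miRNAs. For the pools they were 0.40 to 1.51, 24.2 to 37.6 and 34.8 to 53.5. Differences that had not passed turned sign without pDAB447 plant 05 (0.0447) or pDAB448 plant 03 (0.14) for the level against pDAB448, without pDAB448 plant 05 (-1.67), pDAB448 plant 12 (-0.959) or pDAB449 plant 01 (-0.0522) for the 21 and 22 nt share of pDAB449 against pDAB448, and without pDAB441 plant 04 (-0.563) for the 24-nt share against pDAB443. With a plant left out of 5 against 3 the exact test cannot reach the threshold. Named miRNAs kept direction and call in 126 of 184 other alternatives and lost the call in 58, and named tags in 156 and 20 of 176, with no reversal.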

Other observations

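The tests of the T3 pools were chosen after the result was seen, and the tests of the miRNAs and the splits of the plants were chosen before.

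Small RNAs of aad-1 were of both strands and mostly of 21 and 22 nt. Their antisense share averaged 40.9% in pDAB435, 42.5% in pDAB441, 41.4% in pDAB443, 43.5% in pDAB448 and 42.2% in pDAB449, and 21 and 22 nt held 82.4%, 82.7%, 80.7%, 77.7% and 76.6%. In pDAB447 plants these shares averaged 27.1% (18.3% to 33.4%) and 57.3% (39.4% to 78.9%). In the T3 pools of pDAB447 they averaged 35.8% and 74.7%, with 27.7% and 39.4% in the pool of event 002 and 37.0% to 39.2% and 83.0% to 84.4% in the other 4. Among the pDAB435 plants aad-1 levels ran from 2818 to 32458 RPM, and plants 03 and 12, which had the highest cry1Fa levels, had 32458 and 22283 RPM.

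Cry1Ab reads of 21 and 22 nt and of both strands were seen in the T3 pools of events 010, 012 and 030 and hardly in the pDAB447 plants. Generation, pooling or sequencing run as the whole reason is argued against by the pool of event 002, whose antisense share was 1.48% and which had 0.405 RPM of antisense 21 and 22 nt reads by direct translation with no limit on shared tags. For the antisense share, endogenous tags read as cry stay open. By direct translation the lowest of those 3 pools had 40.9% antisense, but without the limit 55.9%, where plants had up to 75.2%. The lowest level of antisense 21 and 22 nt reads among those pools was 14.2 RPM. That lay little above the 12.6 RPM of a pDAB435 plant, which lacks the gene. Cry1Ab tags by direct translation numbered 89 and 85 in pDAB435 plants 03 and 12, which had the most cry1Fa small RNAs, and 31 to 39 in the other pDAB435 plants. The 12.6 RPM need therefore not be endogenous. Against endogenous tags of that strand and size common to all plants argue levels of at most 0.827 RPM in pDAB447 plants, 0.658 in pDAB441 and 2.92 in pDAB443. It may be that siRNAs of the whole inserted DNA rise and fall together: within groups, antisense 21 and 22 nt reads of cry and aad-1 correlated over 27 libraries (r = 0.786, permutation p = 0.00584; rho = 0.618, permutation p = 0.0157; a single relation tested). Without the 2 farthest libraries r was 0.663 (permutation p = 0.0347) and rho 0.519 (permutation p = 0.0566), and over the 22 plants alone r was 0.475 (permutation p = 0.191) and rho 0.302, so the relation was not shown without the pools.

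Of 21 tested miRNAs 9 were higher in pDAB447 plants than in pDAB448 plants and 14 than in pDAB449 plants, while most other changed tags were lower. RNA quality, as far as the share of full-length reads stands for it, is a candidate explanation: within constructs, plants with a larger share of full-length reads had lower miRNA levels (r = -0.566, permutation p = 0.021, adjusted p = 0.0419; rho = -0.505, permutation p = 0.0458, adjusted p = 0.0915, which misses the threshold; 22 plants, 2 relations tested), and without the 2 farthest plants r was -0.525 (permutation p = 0.0242). Fragments of rRNA and tRNA, the other sign of it, differed by less than their spread (0.927%, 1.02% and 0.994%). Depth stays open, with r = -0.149 (permutation p = 0.604) and rho = -0.0887 (permutation p = 0.741), and so do reads of other lengths, since with tags of 20 to 24 nt 14 calls were made, 1 where there had been 9 (pDAB448) and 13 where there had been 14 (pDAB449). The construct, confounded with its event, stays open as a biological explanation. For miR168 the low groups were pDAB448 and pDAB449, with pDAB447 (2214 RPM) near the cry1Fa constructs (2000 to 2207 RPM). The difference need therefore not lie in pDAB447.

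Other splits of the same plants were compared with the real ones. For pDAB447, the real split gave the most calls against pDAB448 (2095 tags, highest other split 830; 9 miRNAs, highest other 7) and against pDAB449 (1002 tags, highest other 772; 14 miRNAs, highest other 13). In each, 1 of 56 splits was as large, a share under 0.05 but the smallest possible and not adjusted over the contrasts. Chance is thus argued against but not excluded, and the margins for miRNAs were narrow. Chance stays open for pDAB441 against pDAB435 (18 tags, highest other 5149, 8 of 56 splits as large) and pDAB443 against pDAB435 (15 tags, highest other 2713, 4 of 56). Splits that call so many more tags than the real ones point to a structure among the pDAB435 plants. Log tag levels of plants 04 and 05 correlated at 0.878 and those of plants 01, 03 and 12 at 0.832 to 0.849. Pairs across these sets correlated at 0.427 to 0.721. For pDAB441 against pDAB443 (10 tags, highest other 0) and pDAB449 against pDAB448 (2 tags, highest other 0) the 10 splits are too few for a share under 0.05. Where edgeR made 0 miRNA calls (0 to 2 at an unadjusted p under 0.05, and 0 with DESeq2) every split gives as many by construction (56 of 56 or 10 of 10), which decides nothing.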
